A study of Mus musculus with 64 samples.

How the data were processed

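RNA was measured in 64 libraries from progenitor cells sorted from fetal mouse liver. Per the labels' protocols, LSK cells were sorted into lysis buffer after staining for CD45.2, lineage antigens (B220, CD3, Gr-1 and Ter-119), Mac1, c-Kit and Sca-1. cDNA was made and amplified by Smart-seq2, a full-length method that marks neither strand nor molecule, and libraries were made by tagmentation with further amplification. Reads are therefore not independent molecules, and floors and counting intervals given below cover counting error only. The gate labels of the CMP, GMP and MEP libraries write CD177 where the staining protocol lists CD117 (c-Kit). The labels give genotype for every library and sex for the LSK libraries only.

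The deposited values are whole-number read counts per Ensembl gene, 1 column per library, which the authors made with featureCounts on mm10 (GRCm38) per the submitters' processing notes. The aligner, the annotation release and the featureCounts version are not given in the sources used here. The LSK counts list 38924 genes, of which 26316 had reads, and 92 synthetic spike-in RNAs. CMP counts list 15790 genes and 21 spike-ins, GMP counts 27892 genes and 43 spike-ins, and MEP counts 13050 genes and 27 spike-ins. The smallest gene total was 0 reads in LSK, 7 in CMP, 1 in GMP and 11 in MEP, so genes near the floor can be listed in one population and not analysed here in another. Symbols and positions came from GENCODE release M21 on GRCm38, matched by gene identifier; 1317 LSK, 146 CMP, 543 GMP and 120 MEP genes had no match and kept their identifier. Spike-ins were kept out of library sizes and tests.

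Each population was fitted by edgeR 4.0.16 in R 4.3.3 with its 3 genotypes in 1 quasi-likelihood model (robust, TMM factors), without covariates. Genes were kept by filterByExpr at its defaults (minimum count 10, minimum total 15). KO against WT, HET against WT and KO against HET were tested with Benjamini-Hochberg adjustment at 0.05 over all genes kept. Every adjusted p for a gene below is from this edgeR test unless DESeq2 or limma is named. Levels are CPM of the TMM-scaled library. The SE of a log2 fold change is its absolute value divided by the square root of the test's F statistic. It is approximate, above all for genes with few reads in a group. A second model took the 11902 genes listed in all of CMP, GMP and MEP, with 1 mean per population and genotype. It tested differences between KO effects and between WT populations. The KO effects of 6 pairs of populations were correlated across genes, with genotype labels permuted among replicate numbers for reference.

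The 21 gene lists were fixed before the data were examined. They cover primary granules, secondary and tertiary granules, granulocyte-monocyte transcription factors, myeloid receptors, monocytes and macrophages, dendritic cells and antigen presentation, eosinophils, and basophils and mast cells. They also cover erythroid, megakaryocyte, stem cell and lymphoid genes, BAF complex subunits other than Smarcd2, mitosis, DNA replication, p53 targets and the interferon response. The last are the unfolded protein and integrated stress response, immediate early and heat shock genes, hepatocyte genes, and endothelial and stromal genes. Some genes stand in several lists, such as Flt3, Egr1 and Kit. Lists were tested by camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were the alternatives. Counts of lists called rest on the camera adjusted p alone, under 0.05.

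Named genes followed a rule fixed before the data were examined. For KO against WT these are Smarcd2, the 10 largest rises and 10 largest falls among genes that passed with a mean log2 CPM of at least 1, and up to 4 members per list with the smallest unadjusted p. For other comparisons these are the 5 largest rises and falls. Predicted genes were passed over, and some genes that the rule takes are not reported here. A group with no reads was given a floor of 3 counts over the group. For a named gene with 1 to 3 reads in a group, the ratio of pooled reads is given with an exact 95% counting interval.

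Alternatives set before the data were examined were RLE scaling, no or a stricter count filter, and models with only the 2 groups or with WT and HET together. The others were DESeq2 1.42.0, limma voom with quality weights, the title number as a block, sex, the replicate number as a block, and each library left out in turn. Title numbers 19 to 24 and M32 to M34 are called series below. Added after the data were seen were the log2 spike-in share as a covariate, a transcript length index as a covariate, and models without libraries that stood apart. The index is the median log2 level of genes with transcripts above 5000 bases minus the median of genes with transcripts below 1500 bases. Each gene was first centred on its mean over the libraries of the population. Protein-coding genes with a mean of at least 10 CPM were used. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.

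The models were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. For KO against WT, edgeR recovered 85% of genes changed 2-fold and 97% of those changed 4-fold in LSK. It recovered 54% and 96% in CMP, 0% and 0% in GMP, and 1% and 18% in MEP. DESeq2 recovered 1% and 17% in GMP and 12% and 65% in MEP. It also called 14 unchanged genes in GMP, 14 in MEP, 31 in CMP and 12 in LSK, where edgeR called 0, 0, 11 and 7. For the difference between KO effects in GMP and CMP the shares were 0% and 12%, and for GMP against CMP in WT 3% and 33%. With nothing changed between HET and WT, 0 genes were called in each population. The simulated counts held no series and no outlying libraries, so this does not bound false calls in the real ones. Splits of the real HET and WT libraries reached 326 genes in LSK, 21 in CMP, 710 in GMP and 29 in MEP. The biological coefficient of variation was 0.197 in LSK, 0.227 in CMP, 0.684 in GMP and 0.461 in MEP.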

Results

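Smarcd2 encodes a subunit of BAF, the mammalian SWI/SNF complex that remodels chromatin. RNA was measured in progenitors from livers of C57BL/6 fetuses that were wild type (WT), heterozygous (HET) or homozygous mutant (KO) for Smarcd2. The labels give an age between 13 and 14 days post coitum for all libraries but 1 CMP HET library, labelled 14.5 days. LSK cells, a lineage-negative fraction with Sca-1 and c-Kit that holds stem cells and multipotent progenitors, gave 5 WT, 9 HET and 9 KO libraries. Common myeloid progenitors (CMP) gave 3 WT, 7 HET and 4 KO libraries, and granulocyte-monocyte progenitors (GMP) gave 3 WT, 7 HET and 3 KO. Megakaryocyte-erythroid progenitors (MEP) gave 3 WT, 7 HET and 4 KO libraries. Reads in genes ran from 4327582 to 24069833 per LSK library (median 7121219) and from 1577073 to 8092644 in CMP (median 3984674). They ran from 1006090 to 6300070 in GMP (median 3309170) and from 1488328 to 5646315 in MEP. The labels do not state that each library came from a separate fetus, so p-values measure the spread between libraries.

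Smarcd2 was near the floor in every library labelled KO. The gene (ENSMUSG00000078619) lies on chromosome 11 from 106263179 to 106272972, on the minus strand of GRCm38. In LSK it stood at 55.9 ± 8.54 CPM in WT (SD, n = 5), 33.7 ± 14.1 in HET (n = 9) and 1.28 ± 0.411 in KO (n = 9). CMP libraries gave 115 ± 21 in WT (n = 3), 47.1 ± 19.98 in HET (n = 7) and 1.04 ± 0.426 in KO (n = 4). In GMP the levels were 87.8 ± 2.90 (n = 3), 45.2 ± 22.1 (n = 7) and 0.604 ± 0.546 CPM (n = 3), and in MEP 110 ± 23.6 (n = 3), 63.7 ± 11.01 (n = 7) and 1.19 ± 0.616 (n = 4). Log2 fold changes of KO against WT were -5.46 ± 0.25 (SE) in LSK, -6.64 ± 0.45 in CMP, -7.22 ± 0.88 in GMP and -6.42 ± 0.39 in MEP, and every KO library lay below every WT library of its population. HET against WT gave -0.72 in LSK, -1.24 in CMP, -0.93 in GMP and -0.79 in MEP, none of which passed.

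**Figure D1:**
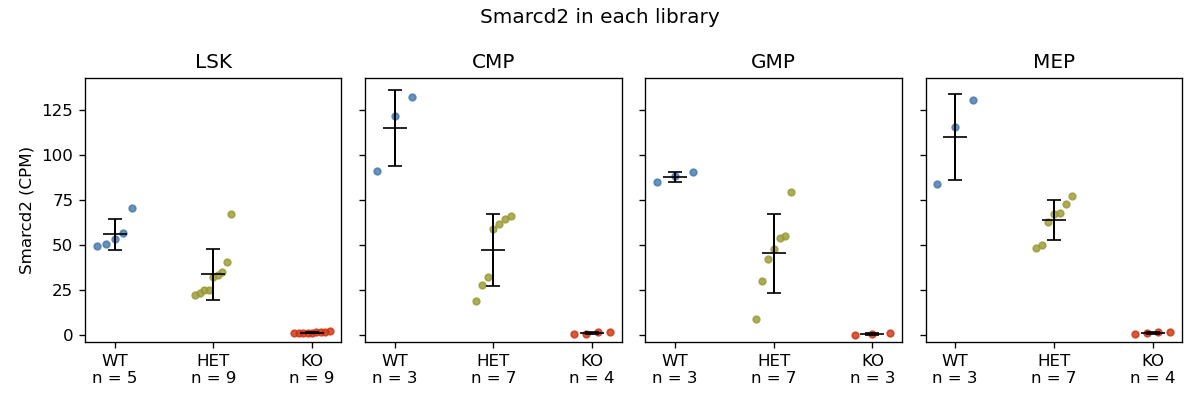
Smarcd2 level (CPM) of each library by genotype in LSK, CMP, GMP and MEP; points are libraries and bars are mean ± SD. KO means lie between 0.604 and 1.28 CPM, and WT means between 55.9 and 115.

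Rsad2, Mx1 and Mycl were higher, and Psmc5 lower, in LSK cells of KO fetuses than in WT cells. Rsad2, which encodes the antiviral protein viperin, rose from 7.47 ± 2.08 CPM (SD, n = 5) to 35.8 ± 14.4 (n = 9), a log2 fold change of 2.26 ± 0.37 (SE; edgeR adjusted p 0.000284), with 9 of 9 KO libraries above every WT library. Mx1, which encodes a GTPase that restricts viruses, rose from 2.22 ± 2.20 to 11.7 ± 5.17 CPM (log2 fold change 2.40; adjusted p 0.00191), with 8 of 9 KO libraries above every WT library. Mycl, a MYC family transcription factor, rose from 2.86 ± 0.241 to 13.9 ± 6.01 CPM (log2 fold change 2.26), in 9 of 9 libraries. Psmc5, an ATPase subunit of the proteasome and a neighbour of Smarcd2, fell from 236 ± 14.0 to 82.0 ± 7.27 CPM (log2 fold change -1.53 ± 0.07; adjusted p 2.06e-15), in 9 of 9 libraries. Of 13878 genes tested, 1322 rose and 1288 fell. At an unadjusted p under 0.05 there were 4454 genes, where chance would give 694.

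The other largest rises in LSK were those of Tmem45a (log2 fold change 2.88), Mx2 (2.48), Ifit3b (2.36), Igfbp5 (2.34), AA467197 (2.33), Bhlhe40 (2.28) and Xkrx (2.24). The other largest falls were those of Folr2, a folate receptor of macrophages (-3.56), Ctsg, a granule protease (-2.72), Colec12 (-2.54), Btla (-1.74), Tcam1, the neighbour of Smarcd2 on its other side (-1.59), Sh2d2a (-1.58), Casp12 (-1.26) and Trib1 (-1.23). The Ctsg call rested on WT library 10 of series 24, with 40.01 CPM against at most 7.66 in the other WT libraries, since without it the adjusted p was 0.206 (edgeR), and limma called neither Ctsg nor Casp12. Colec12 passed in 5 of 14 fits that each left out 1 library, with its highest adjusted p, 0.123, without WT library 8 of series 22. Spike-in reads made up 0.516 ± 0.139% of all reads in WT and 0.781 ± 0.239% in KO. With the spike-in share as a covariate 1612 genes changed, with the length index 1680, and without that library 1684.

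**Figure D2:**
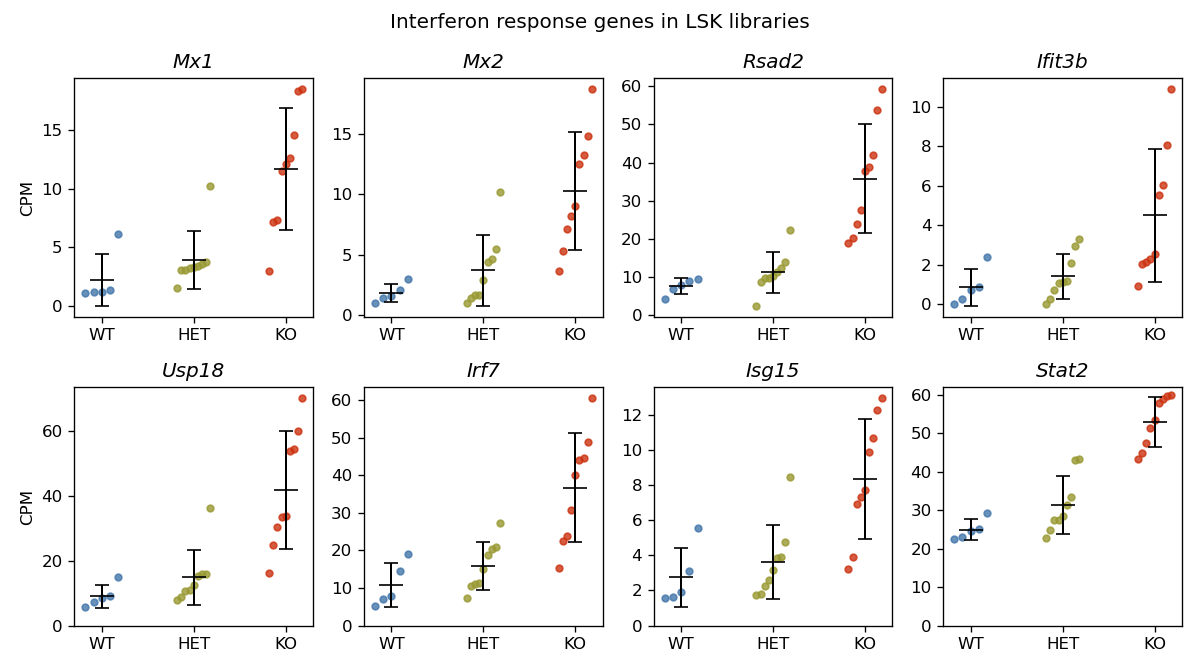
Level (CPM) of 8 interferon response genes in each LSK library by genotype; points are libraries and bars are mean ± SD (WT n = 5, HET n = 9, KO n = 9). The KO mean of Usp18 is 41.9 CPM against 9.06 in WT, and that of Irf7 is 36.7 against 10.8.

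Of 28 interferon response genes tested in LSK, 23 rose and 0 fell, or 28 and 0 adjusted over the list alone. Among them Usp18 (log2 fold change 2.20), Irf7 (1.79) and Isg15 (1.63) encode regulators and effectors of interferon signalling. The camera test gave an adjusted p of 2.48e-21 with the preset correlation, and an adjusted p = 0.107 with an estimated correlation, so the call was lost. Of 10 dendritic cell and antigen presentation genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone), among them Itgax (1.60), H2-Ab1 (1.36) and H2-DMa (1.11). This was the 1 list of 8 whose call held in LSK, with adjusted p 4.17e-07 and 0.0436 with an estimated correlation. Of 25 lymphoid genes 8 rose and 0 fell (13 and 0 adjusted over the list alone), including Il7r (1.74), the receptor for interleukin 7, and Rag2 (1.29), which recombines antigen receptor genes (camera adjusted p 2.19e-06; adjusted p = 0.445 with an estimated correlation). Among 23 p53 targets 6 rose, including the cell cycle inhibitor Cdkn1a (1.35), and Ckap2 (-0.37) fell (7 and 1 adjusted over the list alone; adjusted p 0.0121; adjusted p = 0.106 with an estimated correlation).

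Of 28 unfolded protein and integrated stress response genes tested in LSK, 14 fell, among them Hsp90b1 (log2 fold change -0.58), Hspa5 (-0.55) and Xbp1 (-0.35), and Ddit3 (0.77) rose (15 and 1 adjusted over the list alone; camera adjusted p 0.00138; adjusted p = 0.47 with an estimated correlation). Of 35 DNA replication genes 7 fell and 0 rose, by both adjustments, among them Ccne1 (-0.62) and Rrm2 (-0.55), a subunit of ribonucleotide reductase (adjusted p 0.000205; adjusted p = 0.47 with an estimated correlation). Ccna2 (-0.64) and Ccnb2 (-0.37) were the 2 of 30 mitosis genes that fell, and 1 fell adjusted over the list alone (adjusted p 0.00791; adjusted p = 0.702 with an estimated correlation). Of 30 stem cell genes 6 rose, including Robo4 (0.72) and Meis1 (0.28), and Ctnnal1 (-0.50) fell (7 and 1 adjusted over the list alone; adjusted p 0.0441; adjusted p = 0.57 with an estimated correlation).

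The other 13 lists were not called in LSK. Of 22 granulocyte-monocyte transcription factors 4 rose, including Rara (0.69) and Myb (0.35). Of 21 myeloid receptors 4 rose, including Itgam (0.99) and Kit (0.33). Among primary granule genes 1 of 13 fell (Ctsg), and 1 of 9 secondary and tertiary granule genes rose (Ltb4r1, 1.00). Ccl9 (0.80) rose among 21 monocyte genes and Alox15 (1.86) among 5 eosinophil genes, and 0 of 8 basophil genes passed. Among 28 erythroid genes Gfi1b (0.76) and Aqp1 (0.64) rose and 1 fell, and 2 of 18 megakaryocyte genes rose, including Plek (0.72). Of 25 BAF subunit genes Arid1b (0.73) and Bicral (0.35) rose, while Actl6a (-0.25) and Smarcb1 (-0.18) fell. Ier3 (0.99) rose and Hsph1 (-0.71) fell among 21 immediate early and heat shock genes. Krt18 (0.63) rose and Apoc1 (-1.62) fell among 7 hepatocyte genes. Of 22 endothelial and stromal genes 4 rose, including Pdgfra (2.20) and Pecam1 (0.71).

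In LSK cells of HET fetuses, Psmc5 fell from 236 ± 14.0 CPM (SD, n = 5) to 162 ± 10.9 (n = 9), a log2 fold change of -0.55 ± 0.07 (SE; edgeR adjusted p 0.000109), with 9 of 9 HET libraries below every WT library. It was the 1 gene of 13878 that passed, 1532 had an unadjusted p under 0.05, where chance would give 694, and DESeq2 called 33. Without HET library 6 of series 21, 27 genes passed, and without HET library 5 of series 20, 2. The preset correlation called 8 lists, among them mitosis genes (down, adjusted p 1.42e-08) and interferon response genes (up, adjusted p 6.14e-05). With an estimated correlation the lowest adjusted p was 0.483. Against HET, KO cells had 823 genes higher and 718 lower. Rises were led by Tmem45a (2.62), Bhlhe40 (2.25), Pira2 (1.81), Lilra6 (1.81) and Ankrd37 (1.80), and falls other than Smarcd2 included those of the erythroid gene Alas2 (-3.96), Folr2 (-2.77) and Btla (-1.61). Interferon response genes again rose, 22 of 28 (25 adjusted over the list alone), with adjusted p 2.99e-23 and adjusted p = 0.0814 with an estimated correlation. Of the 8 lists called in this comparison, dendritic cell genes and p53 targets held (adjusted p = 0.0332 each with an estimated correlation).

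Ctsg, Elane, Ly6c2 and S100a8 were lower, and Mycl and Il7r higher, in CMP cells of KO fetuses than in WT cells. Ctsg, which encodes cathepsin G, fell from 424 ± 40.6 CPM (SD, n = 3) to 65.9 ± 11.9 (n = 4), a log2 fold change of -2.68 ± 0.18 (SE; edgeR adjusted p 7.31e-08). Elane, neutrophil elastase, fell from 100 ± 63.2 to 8.98 ± 4.92 CPM (log2 fold change -3.49 ± 0.47; adjusted p 0.000702). Ly6c2, the monocyte surface antigen, fell from 19.32 ± 4.43 to 1.32 ± 1.15 CPM (-4.01; adjusted p 8.13e-06), and S100a8, a calcium-binding protein of neutrophils and monocytes, from 16.8 ± 3.28 to 0.809 ± 1.47 (-4.71; adjusted p 0.00195). Mycl rose from 3.22 ± 2.57 to 35.8 ± 6.72 CPM (3.65; adjusted p 0.000103) and Il7r from 4.03 ± 1.34 to 19.05 ± 1.52 (2.21; adjusted p 0.000441). For each of these genes all 4 KO libraries lay beyond every WT library. Of 11658 genes tested, 119 rose and 96 fell, and 1499 had an unadjusted p under 0.05, where chance would give 583.

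The other largest rises in CMP were those of St8sia1 (log2 fold change 2.71), Shisa8 (2.58), Cds1 (2.33), Tnip3 (2.31), Ckb (2.30), Lair1 (2.29), Fn1 (2.26) and Msrb3 (2.19). C3 (-4.24) and Trem2 (-3.23) fell. Mcpt8, a basophil protease, fell to 1 read over the KO group, a log2 ratio of pooled reads of -6.66 (95% counting interval -11.98 to -4.15), and Apoh, a liver plasma protein, also to 1 read (-6.42; -11.74 to -3.90). S100a9 had 0 reads in KO, at least 25.7-fold lower than WT, and did not pass (adjusted p 0.0656). Without WT library 2, 88 genes changed, and without WT library 5, WT 12, KO 13 or KO 15 the counts were 138, 121, 135 and 136. Without HET 8 the count was 504 (295 rose and 209 fell), with the length index 323, with the spike-in share 136, by DESeq2 559 and by limma 772. Apoh, Lair1 and Tnip3 each passed in 1 of 7 fits without 1 library, C3 in 2 and Trem2 in 3, and limma called neither Apoh nor C3. With the series as a block, to which the 2 KO libraries of M34 add nothing because that series holds no WT, 83 genes changed.

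Of 14 primary granule genes in CMP, 5 fell and 0 rose (7 and 0 adjusted over the list alone), including Prss57 (log2 fold change -2.53), Ctsc (-1.32) and Nkg7 (-1.15), while Mpo did not pass (-0.21). The camera adjusted p was 5.00e-13, and 0.0444 with an estimated correlation. Of 9 secondary and tertiary granule genes 3 fell, S100a8, Hp (-1.48) and Cybb (-1.20), and 0 rose (5 and 1 adjusted over the list alone; adjusted p 7.49e-06, and 0.0280 with an estimated correlation). Lymphoid genes rose in 3 of 15, Il7r, Rag2 (1.40) and Flt3 (1.28), and none fell (4 and 0 adjusted over the list alone; adjusted p 1.60e-05 and 0.0160). Of 9 dendritic cell genes H2-DMa (1.41) and Flt3 rose (5 and 0 adjusted over the list alone; adjusted p 6.41e-05 and 0.0493). Of 19 p53 targets Cdkn1a (1.92), Pmaip1 (1.49) and Btg2 (1.00) rose (4 and 0 adjusted over the list alone; adjusted p 0.000263 and 0.0160). Of 20 interferon response genes Usp18 (2.08), Rtp4 (1.79), Dhx58 (1.28) and Irf9 (0.91) rose and none fell (5 and 0 adjusted over the list alone; adjusted p 1.27e-08 and 0.0444).

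Monocyte genes fell in 3 of 17 in CMP, Ly6c2, Fcgr1 (-2.23) and F13a1 (-2.003), and 0 rose (5 fell and 3 rose adjusted over the list alone; adjusted p 0.000340; adjusted p = 0.0756 with an estimated correlation). Of 26 unfolded protein response genes Ero1l (-1.20), Hsp90b1 (-0.97) and Dnajc3 (-0.71) fell (8 adjusted over the list alone; adjusted p 3.48e-07; adjusted p = 0.0920 with an estimated correlation). Of 19 immediate early genes Egr1 (1.86), Btg2 and Zfp36 (0.99) rose (8 up and 1 down adjusted over the list alone; adjusted p 3.48e-07; adjusted p = 0.0547 with an estimated correlation). Hepatocyte genes had a median log2 fold change of -2.77 over 20 genes, of which Apoh fell and Krt18 (1.49) rose (5 fell and 1 rose adjusted over the list alone; adjusted p 1.52e-07; adjusted p = 0.247 with an estimated correlation). Ccne2 (-1.15) and Rrm2 (-0.90) fell among 35 DNA replication genes, and 0 of 18 megakaryocyte genes passed; these calls had adjusted p 0.0385 and 0.0166, and adjusted p = 0.632 and 0.53 with an estimated correlation. The other 9 lists were not called: Egr1 rose and Nfil3 (-1.39) and Id2 (-1.38) fell among 21 transcription factors, and Itgam (1.84) and Flt3 rose among 18 receptors. Siglecf (1.02) rose among 7 eosinophil genes, Ifitm1 (1.47) rose and Mcpt8 fell among 8 basophil genes, Gfi1b (1.39) rose among 32 erythroid genes, and Mycn (1.12) and Meis1 (0.60) rose among 24 stem cell genes. None of 25 BAF genes (a list without Smarcd2), 30 mitosis and 13 endothelial genes passed.

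CMP cells of HET fetuses had 0 genes past the threshold by edgeR against WT, with 296 at an unadjusted p under 0.05, where chance would give 583, and 1 by DESeq2. The preset correlation called 11 lists, with the lowest adjusted p = 0.347 with an estimated correlation. Against HET, 161 genes rose and 94 fell in KO. Usp18, an interferon-induced protease (2.60), Mycl (2.31), Rtp4 (2.15), Fn1 (2.06) and Tnip3 (1.99) led the rises, and C3 (-4.16), Trem2 (-3.71), Ly6c2 (-3.13), Smarcd2 and Mcpt8 the falls. Of 12 lists called, interferon response (8 of 20 rose, 13 adjusted over the list alone) and p53 targets (adjusted p 0.0117 each) and lymphoid and immediate early genes (0.0498 each) held with an estimated correlation. Primary granule genes, of which 4 of 14 fell (6 adjusted over the list alone), had adjusted p = 0.0824 with an estimated correlation. Without KO library 15, KO 13 or HET 1, 4 or 10 there were 112, 119, 162, 168 and 164 genes, and 415 without HET 8. With the series as a block 64 genes changed, with the spike-in share 95, and by DESeq2 594.

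**Figure D3:**
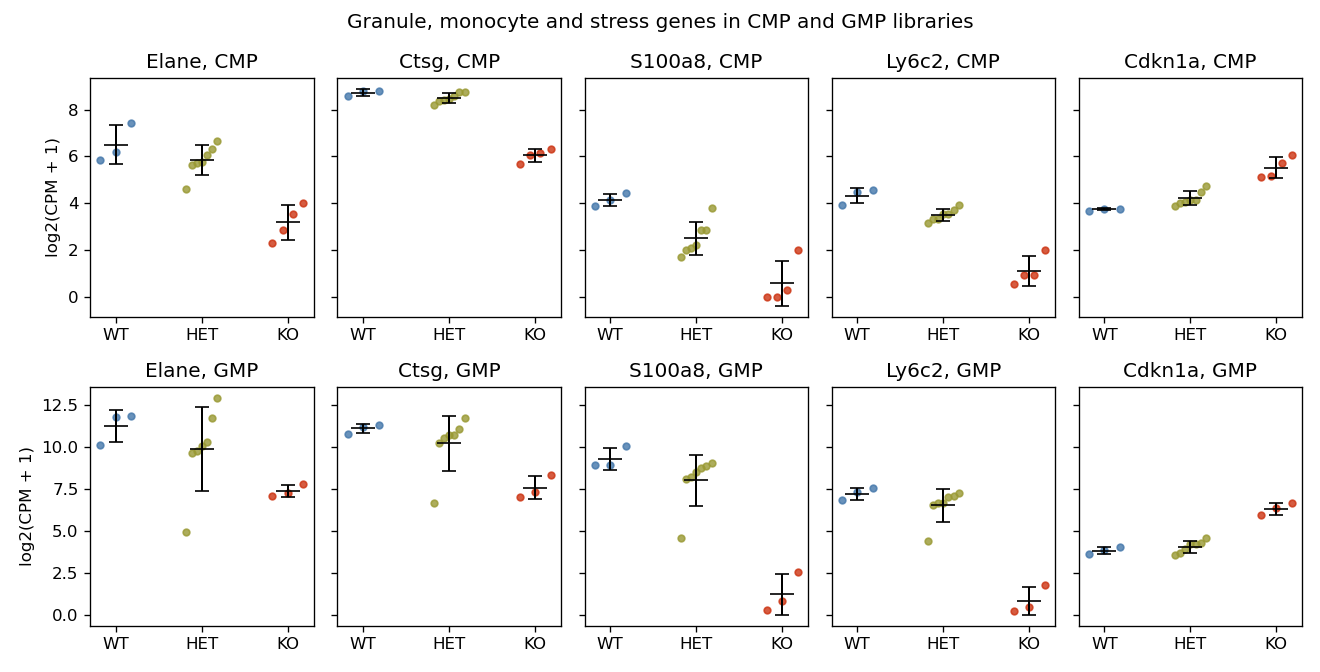
Level, log2(CPM + 1), of Elane, Ctsg, S100a8, Ly6c2 and Cdkn1a in each CMP library (top; WT n = 3, HET n = 7, KO n = 4) and GMP library (bottom; WT n = 3, HET n = 7, KO n = 3); points are libraries and bars are mean ± SD. Ly6c2 averaged 1.32 CPM in CMP KO against 19.32 in WT, and 1.02 in GMP KO against 152.5 in WT; Elane and Ctsg in GMP did not pass the test.

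GMP cells of KO fetuses had few or no reads of S100a8, S100a9, Ly6c2 and Camp. S100a8 fell from 683 ± 336 CPM (SD, n = 3) to 1.97 ± 2.60 (n = 3), a log2 fold change of -8.54 ± 1.27 (SE; edgeR adjusted p 0.00787). S100a9 fell from 115 ± 79.0 to 0.721 ± 0.928 CPM (-7.49; adjusted p 0.00711), and Ly6c2 from 152.5 ± 36.6 to 1.02 ± 1.27 (-7.38; adjusted p 0.00154). Camp, which encodes the antimicrobial peptide cathelicidin, had 15.4 ± 2.16 CPM in WT and no reads in KO, at least 68.0-fold lower with 3 counts over the group as the floor (adjusted p 0.0200). The cell cycle inhibitor Cdkn1a rose from 13.4 ± 1.96 to 80.6 ± 19.52 CPM (2.58; adjusted p 0.0285), and the immediate early factor Egr1 from 10.2 ± 0.748 to 114 ± 48.6 (3.49; adjusted p 0.0200). For these 6 genes all 3 KO libraries lay beyond every WT library. Of 12239 genes tested, 5 rose and 20 fell, and 789 had an unadjusted p under 0.05, where chance would give 612. Limma called 34 genes, of which 22 rose and 12 fell, with 8 of the 25 among them, and called neither S100a9 nor Camp. With WT and HET together 23 rose and 24 fell, all 25 among them.

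The other rises in GMP were those of Prkcq, a protein kinase C (log2 fold change 3.85), Rgs1 (3.66) and Mc5r (3.13). Among falls, Ear1 (-5.71) and Ear2 (-5.40) are near-identical eosinophil ribonuclease paralogs whose reads can be split between copies. Hpse fell to 2 reads over the KO group (log2 ratio of pooled reads -6.67, 95% counting interval -9.72 to -4.79), Btla to 3 (-6.24; -8.53 to -4.68) and Cep83os to 3 (-5.31; -7.61 to -3.72). Spike-ins took 2.76 ± 0.278% of reads in the 3 KO libraries and at most 0.394% in the other GMP libraries. Without WT library 2, 5 or 12 the count was 5 each time, and without KO 6, 13 or 15 it was 6, 222 and 11. With the series as a block, KO 6 alone carries the KO effect, because M34 holds no WT. Most of the named genes then lost their call. DESeq2 called 83 genes, and edgeR 51 with the length index and 1696 with the spike-in share, while limma called none of the 5 falls named here. In the 6 fits without 1 library, Ly6c2 passed in 6, S100a9 and Ear1 in 5, S100a8 in 4, Prkcq in 3, and Cdkn1a, Egr1, Rgs1 and Ear2 in 2. Camp, Hpse, Btla, Cep83os and Mc5r passed in 1 of 6, and Camp had its highest adjusted p, 0.0972, without WT library 5.

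Of 18 secondary and tertiary granule genes in GMP, 3 fell, S100a8, S100a9 and Camp, and 0 rose (6 and 0 adjusted over the list alone). Camera gave adjusted p 5.76e-09, and 0.00830 with an estimated correlation. Of 17 immediate early genes Egr1 rose (4 adjusted over the list alone; adjusted p 1.38e-07, and 0.00235 with an estimated correlation). The transcript length index was -1.46, 0.15 and -1.62 in KO libraries 6, 13 and 15 and -0.42 to 1.03 in WT. Of 19 monocyte genes Ly6c2 fell (4 down and 1 up adjusted over the list alone; adjusted p 0.000391; adjusted p = 0.0752 with an estimated correlation). None of 20 hepatocyte genes passed, and 7 fell and 1 rose adjusted over the list alone (down, adjusted p 8.33e-06; adjusted p = 0.574 with an estimated correlation). Among 12 basophil genes none passed, and 4 rose and 1 fell adjusted over the list alone (up, adjusted p 0.00157; adjusted p = 0.204 with an estimated correlation). Erythroid (32 tested) and unfolded protein response genes (26) were called down at adjusted p 0.0444 and endothelial genes (11) up at 0.0497, each with 0 genes passing and adjusted p = 0.574 with an estimated correlation. The other 13 lists were not called: among 14 primary granule genes 0 passed and 2 fell adjusted over the list alone, with log2 fold changes of -4.06 for Elane and -3.45 for Ctsg. Ear1 and Ear2 fell among 12 eosinophil genes, Egr1 rose among 20 transcription factors and Cdkn1a among 19 p53 targets. No gene passed in the receptor, dendritic cell, megakaryocyte, stem cell, lymphoid, BAF, mitosis, DNA replication or interferon lists.

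GMP cells of HET fetuses had 0 genes past the threshold by edgeR against WT, with 61 at an unadjusted p under 0.05, where chance would give 612, and 0 by DESeq2. The preset correlation called 6 lists, with the lowest adjusted p = 0.176 with an estimated correlation. Against HET, 9 genes rose and 23 fell in KO. Nap1l5 (6.01), Smpx (5.43), Rgs1 (3.33), Prkcq (3.15) and the ribonuclease Rnase6 (2.72) led the rises. S100a8 (-7.55), Ly6c2 (-6.85), S100a9 (-6.60), Smarcd2 (-6.29) and Camp, with no KO reads, led the falls. Of 6 lists called, immediate early genes held (adjusted p 0.00643 with an estimated correlation). Without KO library 13, 431 genes changed, and 12 without KO 15, 19 without KO 6, 57 without HET 7, 18 without HET 4, and 17 without HET 1, 3 or 10. With the series as a block 8 genes changed, with the spike-in share 1193, and by DESeq2 313.

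MEP cells of KO fetuses differed from WT in 1 of 11686 genes tested, Smarcd2, while 809 had an unadjusted p under 0.05, where chance would give 584. Cd79a, a signalling chain of the B cell receptor, did not pass (edgeR adjusted p 0.203), and stood at 92.1, 130 and 27.9 CPM in the WT libraries and at 9.92, 10.6, 9.01 and 3.19 in the KO libraries. Of 28 lymphoid genes 0 passed, and 17 fell and 0 rose adjusted over the list alone, with a median log2 fold change of -2.65 (camera adjusted p 3.07e-25, and 0.0382 with an estimated correlation). Of 19 megakaryocyte genes 3 rose adjusted over the list alone, with a median of 0.75 (adjusted p 7.43e-06, and 0.0382 with an estimated correlation). Calls lost with an estimated correlation were those of 22 hepatocyte genes (median -2.55; adjusted p 1.44e-08; then adjusted p = 0.387), 7 secondary granule genes (4 fell adjusted over the list alone; 1.51e-06; then adjusted p = 0.122) and 12 monocyte genes (4 fell adjusted over the list alone; 8.62e-06; then adjusted p = 0.204). Interferon response genes (17, up; adjusted p 0.0177) and myeloid receptors (13, down; adjusted p 0.0437) gave adjusted p = 0.137 and 0.469 with an estimated correlation. In the 14 other lists no gene passed over all genes.

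DESeq2 called 112 genes and limma 159 between MEP KO and WT, and edgeR called 28 with the length index as a covariate and 32 without HET 8 and KO 15. Without KO library 6, 11 or 15 there were 2 genes, and 11 lists were called without KO 15. MEP cells of HET fetuses had 0 genes past the threshold by edgeR against WT, with 89 at an unadjusted p under 0.05, where chance would give 584, and 0 by DESeq2. The preset correlation called 3 lists, with the lowest adjusted p = 0.481 with an estimated correlation. Against HET, Ifitm1, an interferon-inducible membrane protein, rose (log2 fold change 5.25; edgeR adjusted p 0.00877) and Smarcd2 fell (-5.64). Ifitm1 stood at 115, 165, 233 and 1969 CPM in the KO libraries, 9.93 to 35.1 in HET and 5.03 to 8.66 in WT. Of 7 lists called, megakaryocyte genes (up, adjusted p 0.00183), interferon response genes (up, 0.00440) and lymphoid genes (down, 0.0196) held with an estimated correlation. Without KO library 6, 4 genes passed, with the series as a block 1, with the length index 75, without HET 8 and KO 15 41, and by DESeq2 151. Of 100 splits of these libraries 16 gave as many as the 2 genes.

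**Figure D4:**
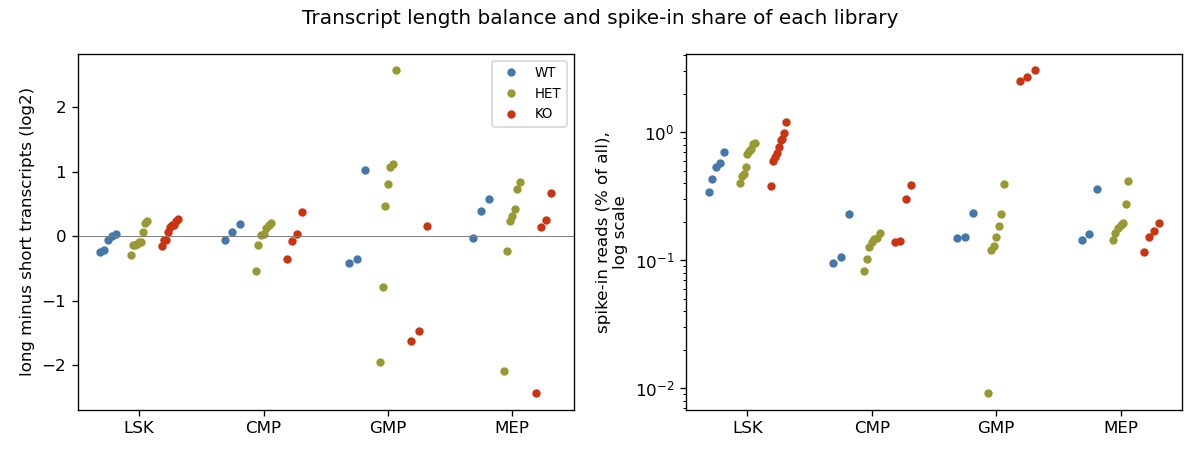
Left, transcript length index (log2 level of long minus short transcripts) and right, spike-in reads as a percent of all reads (log axis), for each library by population; points are libraries coloured by genotype. The 3 GMP KO libraries average 2.76% spike-in reads and no other GMP library exceeds 0.394%; MEP KO library 15 has an index of -2.43.

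KO effects were compared between populations by interaction tests over 11829 genes. Between GMP and CMP, Zfp773, a zinc finger gene (adjusted p 0.00760), and Cep83os (log2 difference -5.04; adjusted p 0.00282) differed. Zfp773 had no reads in GMP KO against 4.67 ± 3.63 CPM in GMP WT, and 6.04 ± 0.408 in CMP KO against 4.68 ± 1.75 in CMP WT. Between GMP and MEP the difference was higher in 26 genes and lower in 23, and 32 genes differed with the replicate number as a block. Of 35 splits of the libraries, 2 gave as many genes here and 8 gave as many between GMP and CMP. Trp53i11 (8.47), Gimap4 (7.73), Id3 (6.29), Trbc2 (5.47) and Adgre1 (5.45) led the first, and Zfp773, Ly6c2 (-6.66), Gramd3 (-6.11), Ppm1k (-5.83) and Dhrs13 (-5.26) the second. Id3, an inhibitor of E proteins, stood at 2.06 ± 1.79 CPM in GMP WT and 18.6 ± 13.9 in GMP KO, against 28.9 ± 25.2 and 2.70 ± 1.45 in MEP. Between CMP and MEP 0 genes differed by edgeR, with 278 at an unadjusted p under 0.05, where chance would give 591, and 10 by DESeq2. Basophil genes were higher in the GMP effect than in the CMP effect (6 tested, 4 adjusted over the list alone; adjusted p 0.0212 with an estimated correlation) and than in MEP (0.00470). Immediate early genes were higher in GMP than in MEP (0.00470), and lymphoid genes in CMP than in MEP (0.00385). Without KO 13, KO 6 or KO 15 the GMP and CMP effects differed in 513, 18 and 7 genes, and without WT 5 or 12 in 1. The GMP and MEP effects differed in 521 without KO 13, 31 without KO 11, and 13, 18 and 17 without WT 2, 5 and 12. Without HET 8 the differences numbered 69 for GMP and CMP and 188 for GMP and MEP, with the length index 71 and 233, and by DESeq2 57 and 96.

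In WT, GMP expressed granule genes at higher levels than CMP. S100a8 stood at 779 ± 419 CPM (n = 3) against 15.4 ± 3.07 (n = 3), Epx, eosinophil peroxidase, at 97.8 ± 10.97 against 2.25 ± 2.76, and Flt3, a receptor of multipotent progenitors, at 1.497 ± 1.37 against 63.7 ± 7.81. Log2 fold changes were 5.66, 5.61 and -5.10, and 80 genes were higher and 42 lower in GMP, among them Ear6 (6.90), Prg3 (5.95), Fcnb (5.56), Mum1l1 (-3.85) and Ifi203 (-3.84). Hpgd and Mycn had 2 reads each in GMP (log2 ratios of pooled reads -6.29, interval -9.35 to -4.42, and -5.20, interval -8.27 to -3.32). Of 14 primary granule genes 6 rose (12 adjusted over the list alone; adjusted p 0.0386 with an estimated correlation), of 11 secondary granule genes 5 and of 7 eosinophil genes 4 (0.00236 each), and 4 of 24 stem cell genes fell (0.0386). Without WT library 5 or 12, 15 and 22 genes differed, and without WT 2, 45 were higher and 107 lower in GMP, while 433 did without HET 8 and 1687 with the length index.

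In WT, Klf1, an erythroid transcription factor, stood at 118 ± 39.7 CPM in MEP against 5.71 ± 4.85 in CMP, and Igll1, a chain of the pre-B cell receptor, at 282.5 ± 197 against 0.285 ± 0.258, while F13a1, a coagulation factor made by monocytes, stood at 8.67 ± 3.58 against 421 ± 103. In all 103 genes were higher and 264 lower in MEP, including Igll1 (9.67), Cd79a (7.91), Clec7a (-5.76), F13a1 (-5.60), Ms4a6c (-5.53), Prtn3 (-5.35) and Clec5a (-5.29). Lef1 and Alpl had 3 reads each in CMP (log2 ratios of pooled reads 7.85, 95% counting interval 6.29 to 10.14, and 7.12, interval 5.55 to 9.40). Of 32 erythroid genes 9 rose (17 adjusted over the list alone; adjusted p 0.00507 with an estimated correlation), and 10 of 22 lymphoid genes rose and 1 fell (0.0152). Against MEP, GMP had 564 genes higher and 258 lower, led by Ly6c2 (8.11), Elane (7.92), Ctsg (7.84), Ms4a3 (7.81), Mpo (7.29) and Igll1 (-8.52). Cd79a and Alpl had no reads in GMP WT, which puts their log2 ratios at -8.15 and -6.59 or lower, and Lef1 had 1 read (-8.91, interval -14.22 to -6.43). All 14 primary granule genes were higher in GMP (adjusted p 0.00163 with an estimated correlation). Without WT 2, 5 or 12, MEP and CMP differed in 190, 239 and 149 genes, and without WT 5 or 12 GMP and MEP in 431 and 335. Without WT 2, 453 genes were higher and 476 lower in GMP than in MEP. Without HET 8 MEP and CMP differed in 655 genes and GMP and MEP in 1576, and with the length index in 865 and 1904.

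Log2 fold changes of KO against WT were correlated across genes for 6 pairs of populations, where genes are not independent replicates. LSK and CMP gave Pearson's r 0.463 and Spearman's rho 0.486 over 11215 genes, against a highest r of 0.388 in 100 permutations of the genotype labels (permutation p 0.0099, the smallest they can give; adjusted p 0.0594). Of genes called in both, 81 rose in both, including Mycl, Il7r, Cdkn1a and Usp18, against 11.7 for independent lists, 21 fell in both, including Ctsg, Btla and Psmc5, against 9.26, and 0 went opposite ways. CMP and GMP gave r 0.434 and rho 0.339, against a permuted maximum of 0.433 (permutation p 0.0286, the smallest that 34 permutations allow; adjusted p 0.0858), with a covariance of 0.229 against a permuted 0.0542. Here 4 genes rose in both, Cdkn1a, Egr1, Prkcq and Rgs1, against 0.0485 for independent lists, and 10 fell in both, including Ly6c2, S100a8 and C3, against 0.118. LSK with GMP (r 0.0669; permutation p 0.238), LSK with MEP (-0.129; 0.891), CMP with MEP (0.274; 0.629) and GMP with MEP (0.412; 0.171) stayed within the permuted range. None of the 6 passed after adjustment. For LSK with CMP and for CMP with GMP the permutation p was already the smallest possible, so the adjusted result does not decide there.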

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

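The length index and the libraries in which it was tested, the choice of genes whose single libraries were examined, and every test of the genes lower in GMP KO were chosen after the data were seen, while the splits of the libraries were planned. Of 97 groups of 4 to 10 libraries examined, 24 held a library far from its group. Chance flags about 1 in 20 groups, or 4.9 of these.

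HET replicate 8 stood apart in 3 populations. In CMP it had 1577070 gene reads to 6 digits against 3696040 or more in the other HET libraries, 15783 genes detected against at most 14116, 30.2% of reads in 1 gene against at most 5.85%, and Mycl at 16.8 CPM against at most 8.31. In GMP it had 27233 genes detected against at most 17575, 48.4% of reads in 1 gene against at most 5.29%, and Egr1 at 40.9 CPM against at most 22.44. In MEP it had a length index of -2.08 against -0.23 or more and Ifitm1 at 35.1 CPM against at most 15.9. MEP KO 15 had a length index of -2.43 against 0.14 or more and Ifitm1 at 1969 CPM against at most 233.

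Mitochondrial genes took 4.145% of reads in CMP KO 15 against 5.07% or more in the other KO libraries, 7.36% in MEP HET 9 against at most 5.89%, and 5.64% in MEP KO 13 against at most 4.78%. S100a8 stood at 12.7 CPM in CMP HET 3 against at most 6.28, and at 3.01 in CMP KO 13 against at most 0.223, and Mycl at 45.8 CPM in CMP KO 15 against at most 33.3. In LSK, HET 5 of series 20 had 24069800 gene reads to 6 digits and Smarcd2 at 67.4 CPM against at most 40.5, and KO 5 of series 19 had 13741400 gene reads. Mx1 stood at 6.15 CPM in WT 2 of series 19 against at most 1.39, and at 10.2 in HET 4 of series 21 against at most 3.79. Ctsg stood at 40.01 CPM in WT 10 of series 24 and at 5.92 in KO 3 of series 20 against at most 2.94. KO effects differed between GMP and CMP in 2 genes and between GMP and MEP in 49, by tests of the difference itself.

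Outside the gene counts, spike-in reads averaged 2.76% in GMP KO. Xist, which is transcribed from the inactive X chromosome, stood at 218 CPM in LSK HET 1 of series 19 and 183 in HET 4 of series 21, both labelled male, so 2 of 23 sex labels did not match.

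The 19 genes other than Smarcd2 that fell in GMP KO had a median log2 fold change of -5.21, the same with Camp at its bound, in libraries with a high spike-in share. Less RNA was tested on 371 genes matched on WT level, which had a median of 0.0648 (quartiles -0.529 and 0.529). That test cannot decide, because scaling centres fold changes near 0 and the fallen genes were left out of the match. It replaced, after its result was known, a test on CMP KO 6 and 11, in which 14 of the genes had a median of -1.64. Spike-ins took 0.141% and 0.138% of reads there, against 0.0958% to 0.230% in CMP WT. The other CMP KO libraries, 13 and 15, had 0.3025% and 0.3885%. These 14 genes were thus also lower in CMP KO 6 and 11, whose spike-in share lay within the WT range. That does not test the GMP libraries, so less RNA stays open for the fall in GMP. Loss of long transcripts is argued against, since with the length index as a covariate 19 of 19 were still called lower. Series M34 is left open too, because KO 6 was the 1 library with WT of its own series, with a median of -4.88 there. So is the makeup of the gate, which was not tested and from which the lineage antibody Gr-1 removes maturing granulocytes.

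Other splits of the same libraries were counted beside each comparison. For LSK KO against WT, 1 of 100 splits, the real one, gave as many genes (2610; highest other 618), and for LSK KO against HET 1 of 100 (1541; 285). For CMP KO against WT it was 1 of 35 (215; 4) and for CMP KO against HET 1 of 100 (255; 118). In these LSK and CMP comparisons the real grouping gave the most genes, by shares not adjusted over the comparisons. For GMP KO against HET it was 2 of 100 (32; 2831), and since another split gave far more genes, chance is not excluded there. The splits moved libraries freely across series, and series M34 holds KO libraries only, so in CMP and GMP they cannot separate genotype from series. For LSK HET against WT, 4 of 100 gave as many (1; highest other 326), a share that rests on Psmc5, next to the targeted gene, and says nothing of other genes. For MEP KO against WT, 1 of 35 gave as many (1; 0), but the 1 gene is Smarcd2, whose loss defines the KO libraries, so this count says nothing of other genes. Chance cannot be excluded for MEP KO against HET, with 16 of 100 (2; 3235), the GMP and MEP effects, with 2 of 35 (49; 593), or the GMP and CMP effects, with 8 of 35 (2; 712). Where the real count is 0, every split is as large by construction and the count decides nothing: this holds for the CMP and MEP effects (35 of 35; highest other 0) and for HET against WT in CMP (100 of 100; 21), GMP (100 of 100; 710) and MEP (100 of 100; 29). The number of lists called was matched by 37 of 100 splits in LSK (8; 14), 2 of 35 in CMP (12; 15) and 2 of 35 in MEP (7; 7), so chance cannot be excluded for these either. For GMP KO against WT (25; highest other 0), its lists (8; 7) and the WT comparisons (122, 367 and 822; 0 each), 10 splits are too few for a share under 0.05, with 1 as large in each. At least 3 times the real count was reached by 15 splits for MEP KO against HET, 3 for the GMP and CMP effects, 2 for LSK HET against WT, and 1 each for GMP KO against HET and the GMP and MEP effects. Such splits point to a structure of the libraries, and which one was not tested.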

How the results depend on the processing

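Smarcd2 passed with RLE scaling, by DESeq2 and in each fit without 1 library, the settings in which it was followed, with log2 fold changes without 1 library from -5.56 to -5.36 in LSK, -6.86 to -6.47 in CMP, -7.73 to -6.57 in GMP and -6.78 to -6.15 in MEP. Within 1.5 times stayed all counts of genes run with RLE scaling, those of KO against WT with the stricter filter, and that of LSK KO against WT with sex, alone or with the series. The spike-in share, the length index and the models without HET 8 (in MEP also KO 15) were chosen after seeing the data. For KO against WT, genes changed were as follows. LSK gave 1612 with the spike-in share, 1680 with the length index, and 1684 to 2675 without 1 library. CMP gave 83 with the series as a block, 424 with 2 groups in the model, 408 with WT and HET together, 559 by DESeq2, 772 by limma, 136 with the spike-in share, 323 with the length index, 504 without HET 8, and 88 to 230 without 1 library. GMP gave 43 without a filter, 3 with the series block, 9 with 2 groups, 47 with WT and HET together, 83 by DESeq2, 34 by limma, 1696 with the spike-in share, which separates KO from all other GMP libraries, 51 with the length index, and 5 to 222 without 1 library. MEP gave 19 with WT and HET together, 112 by DESeq2, 159 by limma, 28 with the length index, 32 without HET 8 and KO 15, and 1 to 2 without 1 library. All 215 CMP genes were among those of DESeq2 and of the length index, and 78 among those of the series block. HET against WT gave 2 genes in LSK without a filter, 2 with the series block, 33 by DESeq2 and 1 to 27 without 1 library, and 1 in CMP by DESeq2. KO against HET gave 1116 to 1702 in LSK without 1 library. CMP gave 64 with the series block, 594 by DESeq2, 95 with the spike-in share and 112 to 415 without 1 library. GMP gave 74 without a filter, 8 with the block, 313 by DESeq2, 1193 with the spike-in share and 12 to 431 without 1 library, and MEP 1 with the block, 151 by DESeq2, 75 with the length index, 41 without HET 8 and KO 15 and 2 to 4 without 1 library. Lists called were 1 in LSK, 6 in CMP, 2 in GMP and 2 in MEP with an estimated correlation, 5 in LSK with the spike-in share, 3 in GMP and 2 in MEP by fry, and without 1 library 6 to 9, 10 to 13, 6 to 9 and 5 to 11. Differences between KO effects were 57, 96 and 10 genes by DESeq2 for GMP and CMP, GMP and MEP, and CMP and MEP. They were 69, 188 and 3 without HET 8, 71, 233 and 3 with the length index, and 1 to 513, 13 to 521 and 0 to 2 without 1 replicate number. GMP against CMP, MEP against CMP and GMP against MEP in WT gave 433, 655 and 1576 genes without HET 8, 1687, 865 and 1904 with the length index, and 15 to 152, 149 to 239 and 335 to 929 without 1 replicate number. Correlations over genes called in either population were 0.693 for LSK and CMP, 0.142 for LSK and GMP, -0.247 for LSK and MEP, 0.806 for CMP and GMP, 0.530 for CMP and MEP and 0.797 for GMP and MEP. These genes were picked by their fold changes in the same libraries and no permuted reference was made, so the values do not measure sharing. No MEP gene other than Smarcd2, which was left out, was called in KO against WT. The GMP and MEP value thus covers 5 rises and 10 falls, all called in GMP. With the replicate number as replicate block, the GMP and MEP effects differed in 32 genes, the GMP and CMP effects in 2, the CMP and MEP effects in 0, and the WT comparisons in 118, 402 and 840. The labels do not say that a number marks a fetus, and not every same-numbered pair deviated together. Correlations were over 0.1 in 9 of 13 CMP and GMP pairs (lowest -0.0708, median 0.134 against 0.00827 for other numbers), 12 of 14 CMP and MEP pairs (-0.0822; 0.217 against -0.0387) and 5 of 13 GMP and MEP pairs (-0.453; -0.0693 against 0.0558). Xist and Y-linked genes gave 1 pattern across the 3 populations for 14 of 14 numbers (8 with Xist), a hint from the data, so whether the numbers mark fetuses stays open. Over the alternatives other than leaving out each library in turn, named genes kept their call in 213 of 228 fits in LSK, 190 of 208 in CMP and 121 of 154 in GMP. With the series block 19 of 19 named genes passed in LSK, 10 of 19 in CMP and 1 of 14 in GMP. For all values that moved the cause was not tested.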

Other observations

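The tests on Psmc5 and the symbol families, and the genes named from the length index, were chosen after the data were seen; the tests on interferon genes were set out before their results were seen, though the spike-in covariate itself was added after seeing the data. Genes of the sorting antigens were compared between KO and WT. In LSK, Itgam, which encodes Mac1, rose by a log2 fold change of 0.99 and Kit by 0.33, while Ly6a, which encodes Sca-1, had 19.58 ± 7.88 CPM in WT and 26.7 ± 9.99 in KO and did not pass (0.46; edgeR adjusted p 0.287). In CMP, Itgam rose from 19.7 ± 4.90 to 69.7 ± 8.51 CPM (1.84), while Kit (0.01), Cd34 (0.28) and Fcgr3 (-0.24) did not pass. None passed in GMP (Kit -0.68, Cd34 0.33, Fcgr3 -0.59) or MEP (Kit 0.00, Cd34 0.45, Fcgr3 -1.73). In MEP, Cd34 lay above every WT library in 4 of 4 KO libraries and Fcgr3 below every WT library in 4 of 4. With the length index as a covariate, GMP KO against WT also called falls of the granule genes Elane (-4.84), Ctsg (-4.09), Nkg7 (-3.07) and Cst7 (-2.19) and rises of Il1rl1 (2.90) and Tgfbi (3.73). MEP KO against WT then called rises of Ifitm1 (4.88) and Slamf1 (1.61) and falls of Gimap4 (-3.98) and Ly6e (-1.96). Of 292 symbol families tested in LSK, 20 of 49 Mrpl genes and 13 of 31 Mrps genes of the mitochondrial ribosome fell, as did 8 of 8 Cct chaperonin genes. None held with an estimated correlation (adjusted p 0.400 each). In GMP and MEP 0 Mrpl and Mrps genes passed, and medians were above 0: 0.71 and 0.57 in GMP (up; camera adjusted p 0.000107 and 0.00423; adjusted p = 0.957 with an estimated correlation) and 1.00 and 1.03 in MEP (up; 1.94e-06 and 0.00330; adjusted p = 0.938). In GMP camera with the preset correlation also called Rpl, Rps, Hist, Cox and Ndufa families up and Zfp and Mapk down. The mean length index was lower in KO than in WT in GMP (-0.97 against 0.09). In MEP (-0.35 against 0.32) the lower KO mean rests on KO 15, at -2.43. KO 11, 13 and 6 stood at 0.26, 0.14 and 0.66 there, and WT libraries at -0.02 to 0.58. The mean index was higher in KO in LSK (0.09 against -0.09). The part of the index in these families was not tested.

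Psmc5 lies 58 bases from Smarcd2 on the other strand, from 106256154 to 106263120, and fell in LSK HET and KO, and Tcam1, 3699 bases from Smarcd2 on the other side, fell in LSK KO from 3.07 to 1.05 CPM (log2 fold change -1.59), with -0.12 in HET, which did not pass. Psmc5 lost 2.76 times the CPM that Smarcd2 had in WT, so reads counted to Smarcd2 are too few to explain the LSK fall. That ratio was taken in LSK only. It does not bound reads running from Smarcd2 into Psmc5, which a method that marks no strand cannot separate. A lower level of the whole region is argued against by the 19 genes tested within 500000 bases, with Tcam1 left out. They had a median log2 fold change of -0.0239 (range -0.33 to 0.75, with 1 lower and 4 higher), and the 20 with Tcam1 had -0.03 (2 fell). An effect of the targeted allele on Psmc5 cannot be told apart from an effect of Smarcd2 dose, because the fall in HET was 48.4% of that in KO and the allele and the dose go together. In CMP Psmc5 also fell (-0.94; edgeR adjusted p 0.00425), while GMP (-0.31) and MEP (-0.21) did not pass.

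The 23 interferon response genes that rose in LSK KO had a median log2 fold change of 1.42. A difference between series is argued against as the whole cause, since 22 still rose with the series as a block (median 1.47) and the median within series was 1.21 (series 19), 1.48 (21), 1.99 (22) and 0.83 (24). The same holds for less RNA, with 19 still called with the spike-in share as a covariate (median 1.17), and for sex, with 23 (median 1.51). That loss of SMARCD2 raises interferon-induced genes is a hypothesis, found and tested on the same libraries. In LSK the camera call of the list was lost with an estimated correlation (adjusted p = 0.107). In CMP 4 of 20 rose and the call held with it, as it did for KO against HET in CMP and MEP. With an estimated correlation the call was lost for KO against HET in LSK and for KO against WT in MEP. No interferon gene passed for KO against WT in GMP or MEP. LSK libraries of other KO and WT fetuses within 1 series would test the hypothesis, and a median near 0 over these 23 genes would count against it.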
